A study of Mus musculus with 6 samples.

How the data were processed

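RNA abundance was measured on 6 Affymetrix expression arrays, 3 of aortic endothelial cell cultures labelled ERK1/2 null and 3 of cultures labelled ERK1/2 wild type. Per the labels' protocols, cells came from mouse aorta, grew in serum-containing medium with endothelial growth supplement and heparin, and gave total RNA that was extracted with Trizol and converted to biotinylated cRNA. The deposited table holds expression on a log2 scale, and per the submitters' processing notes the authors made these values with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes), with no version given. The log2 scale was read from the values, which ranged from 0.74 to 14.32 with 0 missing. RMA compresses differences of dim probe sets, so a log2 difference near the lower end of the range can understate the change. No depth applies to array values, and the number of arrays limited the precision.

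The table had 16775 probe set rows. The platform annotation used here listed 16015 of them, 760 were not listed and so were unnamed here, 1019 named several genes and 14996 named 1 gene. Of these last rows, 14941 had a gene identifier held in the gene table of the mouse assembly GRCm38.p6, which was used for names only; the others kept the name of the platform annotation. Rows with several genes or none were left out of the gene-level tests. Where a gene had several rows (135 genes), the row with the highest mean over the 6 arrays stood for it, and 0 of these genes had rows called in opposite directions. This left 14860 genes. No row used here named the 2 targeted kinase genes, which were not analysed here, so the labels could not be checked by the level of the deleted gene.

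Groups were taken from the sample titles. Differences between ERK1/2 null and wild type were tested per gene with the linear models and empirical Bayes moderation of limma 3.58.1 (lmFit and eBayes) in R 4.3.3, on the deposited values, 2-sided, with Benjamini-Hochberg adjustment over the 14860 genes, and a gene was called at an adjusted p under 0.05. Tables were joined with Python 3.11.15 and pandas 2.3.3. A set of 22 gene lists (455 genes written, 390 measured) covered outputs of the pathway, the cell cycle, growth, matrix, inflammation, metabolism, and markers of endothelial and other cells an aortic culture can hold. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Camera was repeated with the correlation estimated from the residuals of each list, which rests on few residual degrees of freedom in a design of 6 arrays, and with fry, which tests whether the genes of a list move on balance in 1 direction. Groups, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined.

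Genes named in the text were the 8 largest increases and the 8 largest decreases among called genes whose groups did not overlap (gene models without a proper symbol left out), up to 3 called members with the largest difference of each list called by camera, up to 2 of each other list, the member with the lowest p where no member of a list was called, and the gene with the lowest adjusted p in each direction (of tied genes, the one with the lowest unadjusted p). This rule gave 55 genes. Further list members are named where 5 or fewer were called or where they carry a list's difference, and these were chosen after their values were seen.

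The titles call the samples biological replicates and number them 1 to 3 in each group, and no label says whether arrays of the same number share an animal, an isolation or a day. Deviations from the group means correlated between arrays of the same number (r across genes of 0.56, 0.34 and 0.44 for numbers 1, 2 and 3), while every pair of arrays with different numbers in the 2 groups stayed at 0.04 or lower. The deviations of a group sum to 0, so positive values for equal numbers push the others down, and the low values are no separate evidence. The numbers were therefore taken to pair the arrays, and a fit with the number as a block is given beside a result where it changed a call or moved a count by more than 1.5 times. The main fit, set before the data were examined, had no block. Unless the block is named, counts, SEs, p-values and fits without an array come from fits without it, where differences between pairs add to the residual spread. With the block, 2479 genes were called.

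Alternatives were quantile normalization, subtraction of each array's median, a filter on the level, an intensity trend with a robust prior, array weights, other rules for several probe sets of a gene, the replicate block, leaving out each array, a stricter threshold and other set tests. A fit without replicate 1 of both groups, the block with an estimated correlation and the block without each pair were added after the data were seen. The procedure was tested on simulated data with the 14860 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. Without the block it recovered 27% of genes changed by 1 on the log2 scale and 77% of those changed by 2, with 1 false call among 105; with the block it recovered 30% and 75%, with 2 false calls among 107. No recovered gene had the wrong sign. The simulated noise within pairs was independent between genes, and far fewer genes were changed than the 1705 called in the data. The shares recovered and the false calls can therefore differ in the data.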

Results

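Endothelial cells isolated from the aorta of 4 week old mice (strain C57/BL6, 5 generations) were infected with a lentivirus and cultured. The design compared cells labelled as lacking the extracellular signal-regulated kinases ERK1 and ERK2, which carry growth factor signals from the cell surface to the nucleus, with cells labelled wild type. The cultures labelled ERK1/2 null received a virus encoding Cre recombinase (3 arrays) and those labelled wild type a virus encoding green fluorescent protein without Cre (3 arrays). The genotype label names an egfp-Cre virus for null replicate 1 and a Cre virus for null replicates 2 and 3, whereas the source label names egfp-Cre for all 3, and they were treated as 1 group. The genotype label gives a homozygous Erk1 deletion with floxed Erk2 for both groups, although the titles and descriptions call the second group wild type for ERK1/2. Read by that label, the groups differ in the Cre-dependent loss of Erk2 and in Cre itself. The group names of the titles are used throughout. Array medians over all probe sets were 6.13, 6.26 and 6.27 on the log2 scale for ERK1/2 null replicates 1, 2 and 3, and 6.12, 6.20 and 6.09 for wild type. Arrays of a group correlated at 0.975 to 0.986 across probe sets. The first principal component (49.6% of the variance) separated the groups and the second (26.0%) separated replicate 1 of both groups from replicates 2 and 3.

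The comparison asked which transcripts differ between cultures labelled ERK1/2 null and cultures labelled wild type. Genes of DNA replication, mitosis and ribosome assembly fell together in ERK1/2 null cultures, with list medians between −0.94 and −2.25 on the log2 scale. The proliferation marker Mki67 was 6.78-fold lower (7.06 ± 0.16 against 9.82 ± 0.02, SD, n = 3 each). The proteoglycan gene Prelp had the largest increase among called genes, at 42.5-fold (11.29 ± 0.80 against 5.88 ± 0.69). By camera at the preset correlation of 0.01, negative feedback regulators of the ERK pathway were lower as a list, with 3 of 11 called. Lists of interferon-stimulated genes, fibroblast markers, smooth muscle markers and angiogenic genes were higher as groups by the same test. The correlations estimated from residuals were 0.82, 0.36, 0.10 and −0.03 for these higher lists in that order. With an estimated correlation neither the feedback list nor any of these higher lists was called. Endothelial markers gave no call as a list and 0 of its 26 members passed. Of these markers 16 lay in the dimmest 33.3% of genes, where a fall would hardly show. With limma, 1705 of 14860 genes differed (11.5%), 795 higher and 910 lower in ERK1/2 null, and 792 of them by at least 2-fold (375 higher, 417 lower). With the replicate block 1326 were higher and 1153 lower, and at 2-fold 580 and 504, so that the majority of calls turned from lower to higher. In all 1705 the 3 null arrays lay on 1 side of the 3 wild type arrays, which the threshold nearly requires with 3 arrays each. Of all tested genes 31.0% did so. By chance 10% would if all 6 arrays were exchangeable, a share that differences between pairs would alter. The count of 1705 fell whichever array was left out. It was 1275, 730 and 880 without null replicates 1, 2 and 3, and 1331, 1036 and 897 without wild type replicates 1, 2 and 3. Fewer arrays leave fewer degrees of freedom, and this was not separated from the weight of single arrays. Camera called 8 of the 22 gene lists, and 1 of them, ribosome biogenesis, with an estimated correlation.

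**Figure D1:**
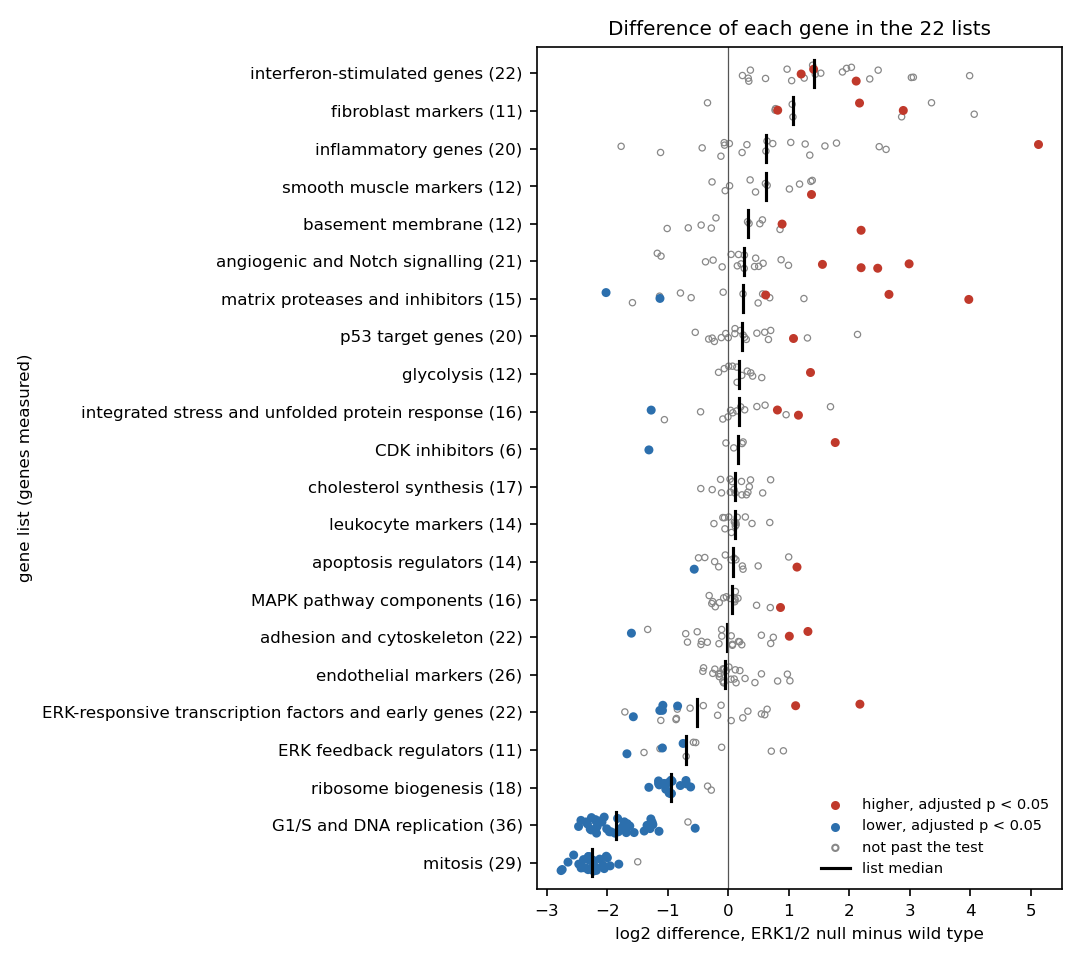
Log2 difference (ERK1/2 null minus wild type, horizontal axis) of every measured gene of the 22 lists, with the number of genes in brackets. Filled points passed the adjusted threshold of 0.05 (red higher, blue lower), open points did not, and the black bar is the list median, which runs from −2.25 for mitosis to 1.43 for interferon-stimulated genes.

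The 8 largest increases were Prelp (log2 difference 5.41, SE 0.49, limma adjusted p = 0.0025), Saa3, Lbp, Hp, Fbln5, Vnn1, Serping1 and Cemip, between 5.41 and 4.13. Saa3, Lbp and Hp encode the acute-phase proteins serum amyloid A3, lipopolysaccharide-binding protein and haptoglobin, and rose 34.9-fold, 25.7-fold and 19.3-fold. Fbln5, which encodes an elastic fibre glycoprotein, rose from 8.47 ± 0.54 to 12.74 ± 0.06 (SD, n = 3; log2 difference 4.26, SE 0.27, limma adjusted p = 0.0014). Vnn1, the pantetheinase vanin 1, rose 18.0-fold, Serping1, the inhibitor of complement C1, 17.7-fold, and Cemip, a hyaluronan-degrading protein, 17.4-fold. Saa3, Hp and Cemip had wild type SDs of 1.96, 1.43 and 1.76, and their adjusted p rose to 0.104, 0.083 and 0.129 without null replicate 2. Vegfd, a ligand of the lymphatic growth factor receptor, shared the lowest adjusted p among increases with Fbln5, Ndrg1 and Sema3b (12.90 ± 0.15 against 9.84 ± 0.26, SD, n = 3; log2 difference 3.06, SE 0.17, limma adjusted p = 0.0014).

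The 8 largest decreases were Mki67 (log2 difference −2.76, SE 0.12, limma adjusted p = 0.0014, the lowest among decreases and shared with other genes), Bub1, Pbk, Cenpe, Klhl1, Lipg, Prkg2 and E2f8, between −2.76 and −2.61. Bub1 is a spindle checkpoint kinase, Cenpe a kinetochore motor, Pbk a kinase of dividing cells and E2f8 an E2F family repressor, and their log2 differences were −2.74, −2.65, −2.66 and −2.61. Lipg, which encodes endothelial lipase, fell by 2.62 (SE 0.50, limma adjusted p = 0.023), and Prkg2, a cGMP-dependent protein kinase, fell by 2.61 (SE 0.28, limma adjusted p = 0.0040). Klhl1, a kelch-like actin-binding protein gene, fell by 2.65, and its adjusted p of 0.036 went over the threshold without any of 5 single arrays, up to 0.110 without null replicate 2. Lipg reached an adjusted p of 0.087 without null replicate 2.

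**Figure D2:**
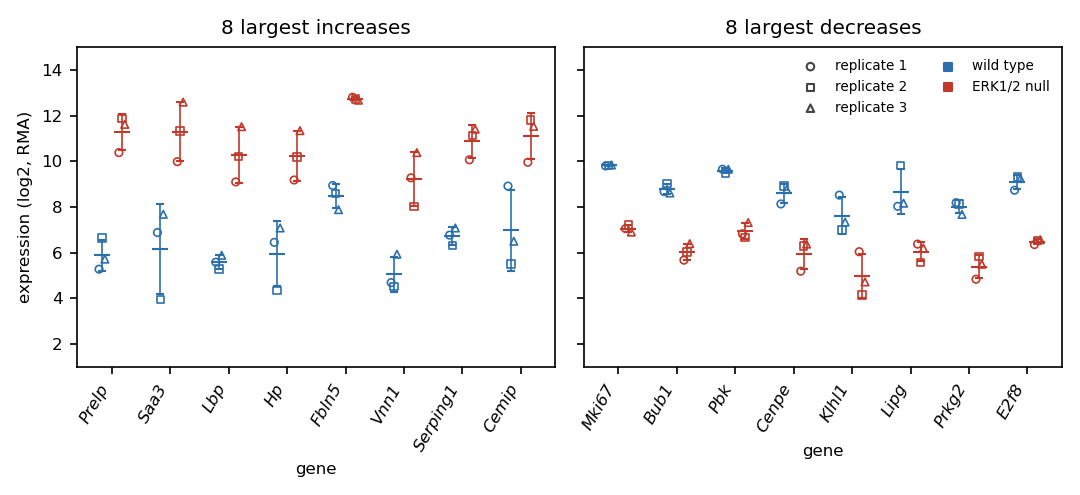
Expression (log2, RMA, vertical axis) of the 8 genes with the largest increase and the 8 with the largest decrease, for wild type (blue) and ERK1/2 null (red). Each symbol is an array, the horizontal bar the mean and the vertical bar ± 1 SD of 3 arrays; the null and wild type arrays do not overlap for any of these genes, as the choice of genes required.

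Feedback regulators of ERK signalling, phosphatases and adaptors whose transcription ERK activity drives, had a median log2 difference of −0.69 over 11 measured genes (camera adjusted p = 0.0057; adjusted p = 0.16 with an estimated correlation). Of these 11, 3 fell and none rose, 8 did not pass, and 8 were lower and 2 higher when adjusted over the list alone; with the replicate block, 5 fell and 2 rose, and 8 were lower within all 3 pairs. Dusp6, the cytoplasmic ERK phosphatase, fell 3.19-fold (8.55 ± 0.44 against 10.22 ± 0.19, SD, n = 3; log2 difference −1.67, SE 0.24, limma adjusted p = 0.0095). The Raf inhibitor gene Spred1 fell by 1.09 (SE 0.11, limma adjusted p = 0.0033) and the phosphatase gene Dusp7 fell by 0.74, with an adjusted p of 0.038 that went over the threshold whichever array was left out, up to 0.113 without null replicate 2. The 2 feedback genes that rose with the block were Spry1 (log2 difference 0.71, adjusted p = 0.14, blocked 0.035) and Il17rd (0.91, adjusted p = 0.057, blocked 0.024).

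ERK-responsive transcription factors and early genes moved in both directions. Of 22 measured, 5 fell and 2 rose (6 and 2 when adjusted over the list alone; 8 and 3 with the replicate block). The list median was −0.52, and camera gave an adjusted p of 0.067 without and 0.027 with the block (adjusted p = 0.44 with the block and an estimated correlation). Fosl1, an AP-1 subunit, fell by 1.57 (SE 0.17, limma adjusted p = 0.0039), and Egr1, Myc, Etv5 and Ier2 fell too (log2 differences −1.13, −1.09, −1.08 and −0.84). Atf3, a stress-induced transcription factor, rose by 2.18 (SE 0.31, limma adjusted p = 0.0089) and the AP-1 subunit Fosl2 by 1.12 (limma adjusted p = 0.024). Among 16 other components of MAP kinase pathways the median was 0.07 (camera adjusted p = 0.88). The kinase Mknk1 alone passed, also when adjusted over the list alone (log2 difference 0.85, SE 0.18, limma adjusted p = 0.031, and 0.110 without null replicate 2), and with the replicate block the scaffold Ksr1 did too (0.70, blocked limma adjusted p = 0.038).

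Cell-cycle genes had the largest list medians in size among the 22 lists. Of 36 genes of the G1/S transition and DNA replication 35 fell (36 when adjusted over the list alone), with a median of −1.85 (camera adjusted p = 4.8e-35; adjusted p = 0.068 with an estimated correlation). Cyclin E2 (Ccne2), the replication licensing factor Cdc6 and Uhrf1, which maintains DNA methylation, had log2 differences of −2.47 (SE 0.32), −2.43 (SE 0.21) and −2.35 (SE 0.16), with limma adjusted p of 0.0074, 0.0021 and 0.0015. The member that did not pass was E2f1 (log2 difference −0.66, limma adjusted p = 0.070). Of 29 mitotic genes 27 fell (29 when adjusted over the list alone), with a median of −2.25 (camera adjusted p = 2.2e-30; adjusted p = 0.16 with an estimated correlation). Those not past the threshold, Ccnb2 (−2.07, limma adjusted p = 0.060) and Ube2c (−1.49, 0.091), passed with the replicate block (0.0023 and 0.021). All 65 genes of both lists were lower within all 3 pairs.

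Ribosome biogenesis genes fell by smaller amounts, 16 of 18 (16 when adjusted over the list alone) with a median of −0.94 (camera adjusted p = 7.3e-16; adjusted p = 0.019 with an estimated correlation, and 0.34 when the block was added). Nop58, a small nucleolar ribonucleoprotein component, fell by 1.31 (SE 0.18, limma adjusted p = 0.0089), and Polr1b, a subunit of RNA polymerase I, and the processing factor Wdr12 each fell by 1.15. Polr1b reached an adjusted p of 0.057 without wild type replicate 3. Of 6 inhibitors of cyclin-dependent kinases, Cdkn2b rose (log2 difference 1.77, SE 0.29, limma adjusted p = 0.014) and Cdkn2c fell by 1.31 (SE 0.21, limma adjusted p = 0.013), the counts being 1 and 1 also when adjusted over the list alone (camera adjusted p = 0.67). Without null replicate 2 their adjusted p were 0.061 and 0.057. Cdkn1a, which encodes p21, differed by 0.25 (limma adjusted p = 0.24).

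Among 20 target genes of p53 the median was 0.22 (camera adjusted p = 0.28). Btg2, an antiproliferative gene, rose by 1.07 (SE 0.21, limma adjusted p = 0.027, and 0.093 without wild type replicate 3), and 3 rose and 1 fell when adjusted over the list alone. With the replicate block 5 rose (Btg2, Fas, Gadd45a, Trp53inp1 and Sesn1) and Mdm2 fell. Of 14 apoptosis regulators the death agonist Bid rose by 1.14 (SE 0.22, limma adjusted p = 0.022) and the initiator caspase gene Casp8 fell by 0.56 (SE 0.13, limma adjusted p = 0.042), with 2 higher and 1 lower when adjusted over the list alone (median 0.07, camera adjusted p = 0.80). With the replicate block Bmf rose in addition (limma adjusted p = 0.072, blocked 0.041). Without null replicate 2 the adjusted p of Bid and Casp8 were 0.086 and 0.123.

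The fibroblast and smooth muscle marker lists were called higher in ERK1/2 null cultures. The 11 fibroblast markers had a median log2 difference of 1.07 and a mean of 1.78 (camera adjusted p = 0.0010; adjusted p = 0.46 with an estimated correlation). Of these, 3 rose and none fell (6 when adjusted over the list alone, 8 with the replicate block), and 10 were higher within all 3 pairs, whose medians were 0.83, 1.38 and 1.67. Mfap5, a microfibril component, rose by 2.89 (SE 0.69, limma adjusted p = 0.047), the collagen gene Col3a1 by 2.17 (SE 0.26, limma adjusted p = 0.0059) and Col1a2 by 0.82 (SE 0.18, limma adjusted p = 0.036). Mfap5 reached an adjusted p of 0.150 without null replicate 2, and Col1a2 0.110 without null replicate 3, 0.071 after quantile normalization and 0.066 after subtraction of array medians. Fibroblast markers stood at a median level of 8.36 in wild type and 10.36 in ERK1/2 null arrays. The 12 smooth muscle markers had a median of 0.63 (camera adjusted p = 0.014; adjusted p = 0.40 with an estimated correlation), and lost the call without null replicate 1 (adjusted p = 0.077), without wild type replicate 2 (0.067), without replicate 1 of both groups (0.0505) and with the filter on level (0.24). The myosin kinase gene Mylk alone rose (log2 difference 1.37, SE 0.24, limma adjusted p = 0.018, and 0.060 without null replicate 3), with 6 higher when adjusted over the list alone and 5 with the replicate block.

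Matrix-modifying genes changed in both directions. Of 15 proteases and inhibitors 3 rose and 2 fell (4 and 2 when adjusted over the list alone, 5 and 3 with the replicate block; median 0.25, camera adjusted p = 0.45). The aggrecanase genes Adamts5 and Adamts1 rose 15.8-fold and 6.31-fold (log2 differences 3.98, SE 0.41, and 2.66, SE 0.31; limma adjusted p = 0.0036 and 0.0053) and the inhibitor Timp2 by 0.62 (limma adjusted p = 0.020), while stromelysin (Mmp3) fell by 2.02 and the urokinase receptor gene Plaur fell by 1.13 (limma adjusted p = 0.047 and 0.048). Of 12 basement membrane genes Nid2 rose by 2.20 (SE 0.14, limma adjusted p = 0.0015) and Sparc by 0.89 (SE 0.10, limma adjusted p = 0.0052), with 3 higher and 2 lower when adjusted over the list alone, and 2 higher and 2 lower (Col15a1 and Col18a1) with the replicate block (median 0.33, camera adjusted p = 0.30). Of 22 adhesion and cytoskeleton genes the integrin subunit gene Itga6 fell by 1.60 (SE 0.31, limma adjusted p = 0.023), and Itgb5 rose by 1.32 (SE 0.30, limma adjusted p = 0.040) with the small GTPase gene Rhob (1.01, limma adjusted p = 0.032). These were 2 higher and 1 lower also when adjusted over the list alone, and 3 and 3 with the replicate block (median −0.03, camera adjusted p = 0.88). Without single arrays the adjusted p of Itga6 rose to 0.079 (null replicate 3) and that of Itgb5 to 0.112 (wild type replicate 3), and Itgb5 lost the threshold after quantile normalization (0.056) and subtraction of array medians (0.063).

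Interferon-stimulated genes were higher as a list, by amounts that differed between pairs. The median over 22 genes was 1.43 (camera adjusted p = 3.6e-05; adjusted p = 0.76 with an estimated correlation), and 21 of them were higher within all 3 pairs, whose medians were 1.44, 1.10 and 2.03. Without the block 3 rose, also when adjusted over the list alone, and with it 14 did. The transcription factor genes Stat2 and Irf9 rose by 2.12 (SE 0.48, limma adjusted p = 0.039, blocked 0.0057) and 1.41 (SE 0.34, limma adjusted p = 0.045, blocked 0.0035), and the immunoproteasome subunit gene Psmb9 by 1.21 (SE 0.29, limma adjusted p = 0.047, blocked 0.012). Without the block these calls lay near the threshold, and each was kept in 1 of 6 fits that left out an array. Stat2 reached a limma adjusted p of 0.114 and Psmb9 0.124 without wild type replicate 2, and Irf9 0.122 without null replicate 3. Their log2 differences in these fits stayed at 1.69 to 2.62 (Stat2), 1.19 to 1.71 (Irf9) and 0.96 to 1.46 (Psmb9). Irf9 and Psmb9 lost the threshold after subtraction of array medians (0.061 and 0.062) and quantile normalization (0.054 and 0.068). With array weights Stat2 and Psmb9 lost it (0.0501 and 0.054). Ifit1 had the largest difference of the list without passing (3.99, limma adjusted p = 0.10, blocked 0.0086). Of 20 inflammatory genes Saa3 alone rose, with a list median of 0.63 (camera adjusted p = 0.28; 0.027 with the block, and adjusted p = 0.62 with the block and an estimated correlation). None passed when adjusted over the list alone, whereas with the replicate block 7 rose and 2 fell, the prostaglandin synthase gene Ptgs2 (−1.77, blocked limma adjusted p = 0.033) and E-selectin (Sele, −1.12, 0.039).

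Endothelial markers were not called in either direction. Over 26 genes the median log2 difference was −0.05 and the mean 0.09 (camera adjusted p = 0.88, direction up), and 0 passed over all genes or when adjusted over the list alone. At an unadjusted limma p under 0.05, 3 of the 26 endothelial markers and 3825 of all 14860 genes differed. Ramp2, a co-receptor of adrenomedullin, had the lowest p (log2 difference 1.02, SE 0.27, limma adjusted p = 0.060). With the replicate block Ramp2, Erg and Flt1 rose (limma adjusted p = 0.013, 0.034 and 0.016). The list's median level was 4.16 in wild type and 4.13 in ERK1/2 null arrays, beside array medians of 6.09 to 6.27. Leukocyte markers (14 genes) had median levels of 3.36 and 3.59 and a median difference of 0.11 (camera adjusted p = 0.59), and 0 passed, also when adjusted over the list alone or at an unadjusted limma p under 0.05. Fcer1g had the lowest p (0.39, SE 0.18, limma adjusted p = 0.23), and with the block Cd14 rose (0.69, limma adjusted p = 0.023).

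**Figure D3:**
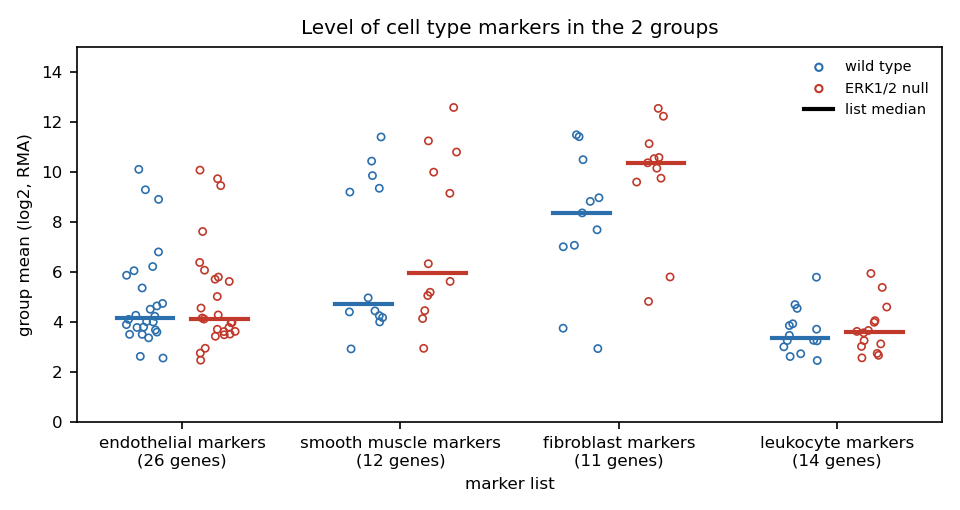
Mean level (log2, RMA, vertical axis) of each marker gene in wild type (blue) and ERK1/2 null (red) arrays for the endothelial, smooth muscle, fibroblast and leukocyte lists; horizontal bars are list medians. Endothelial medians are 4.16 and 4.13 and fibroblast medians 8.36 and 10.36 in wild type and null.

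Angiogenic and Notch pathway genes were higher as a list, carried by a few members. The median over 21 genes was 0.27 (camera adjusted p = 0.042; adjusted p = 0.25 with an estimated correlation), and 4 rose and none fell, over all genes and when adjusted over the list alone. With the replicate block 4 rose and Esm1 fell (log2 difference −1.11, limma adjusted p = 0.69, blocked 0.025). The Notch ligand gene Jag1 rose by 2.99 (SE 0.55, limma adjusted p = 0.020), angiopoietin 2 (Angpt2) by 2.47 (SE 0.49, limma adjusted p = 0.025), Nid2 by 2.20 and the Notch target Hes1 by 1.56 (limma adjusted p = 0.0073). The list call was lost without null replicate 3 (adjusted p = 0.075), without wild type replicate 2 (0.110), after quantile normalization (0.052) and with the filter on level (0.054), and Jag1 and Angpt2 reached 0.077 (without null replicate 2) and 0.083 (without wild type replicate 3).

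Metabolic and stress lists were not called. Of 17 cholesterol synthesis genes 0 passed, also when adjusted over the list alone (3 at an unadjusted limma p under 0.05), with a median of 0.11 (camera adjusted p = 0.45), and Hmgcs1 had the lowest p (0.70, SE 0.18, limma adjusted p = 0.059). Of 12 glycolysis genes Pfkfb3, which makes an activator of phosphofructokinase, rose (1.35, SE 0.33, limma adjusted p = 0.0499, but 0.052 with an intensity trend and 0.139 without wild type replicate 3), and 0 passed when adjusted over the list alone (median 0.19, camera adjusted p = 0.33). Of 16 genes of the integrated stress and unfolded protein responses the pseudokinase gene Trib3 rose by 1.16 (SE 0.17, limma adjusted p = 0.010) and Chac1 by 0.81 (limma adjusted p = 0.044), and the serine pathway enzyme gene Shmt2 fell by 1.27 (SE 0.23, limma adjusted p = 0.020, and 0.079 without null replicate 2). These were 2 higher and 1 lower also when adjusted over the list alone, and 3 and 2 with the replicate block (median 0.17, camera adjusted p = 0.28).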

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

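The test of other splits was set before its outcome was seen, and the cell-cycle tests given here were chosen after the result was seen.

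Probe sets without a single gene name lay outside the gene-level comparison, and they held a signal between the groups. Tested together with all 16775 probe sets in limma, 126 of 1779 such probe sets differed (7.08%), 59 higher and 67 lower in ERK1/2 null. The largest differences belonged to probe sets 6836728 (3.59, SE 0.58) and 6856290 (3.52, SE 0.68) among the higher and 6748888 (−3.04, SE 0.64) and 6815558 (−2.90, SE 0.42) among the lower, with limma adjusted p of 0.015, 0.025, 0.033 and 0.011.

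The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1705 changed genes and the highest other split 0, so that 1 of the 10 reached the real count. The same held for genes changed at least 2-fold (792 against 0, again 1 of 10). Among the 4 splits that part all 3 numbered pairs, the real one gave 2479 genes with the replicate block and the other 3 gave 0. Every other split puts null and wild type arrays on the same side, so that a group difference adds to its residual spread. Few or no called genes follow from this, and the counts of 0 do not show what chance alone would give. For gene lists the real split called 8 lists and another split 10, and 3 of the 10 splits called at least 8. Both other splits of these 3 kept replicate 1 of the 2 groups on the same side and so parted 1 pair only. Among the 4 splits that part all 3 pairs the real one called 8 lists and the others 3, 6 and 5. The camera p of the G1/S, mitosis, ribosome biogenesis, ERK feedback and angiogenic lists was smaller in the real split than in each of the 9 others, while 1 other split matched or passed that of the fibroblast list, 2 that of the smooth muscle list and 3 that of the interferon list.

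The fall of cell-cycle genes was set beside scaling and a response to Cre. Quantile normalization left the median of the 65 cell-cycle genes at −2.15, against −2.12 with the deposited values. It could hardly have done otherwise on values that RMA had already normalized between arrays, so it is no separate evidence. Array medians lay between 6.09 and 6.27, too close for scaling left after RMA to give a fall of this size. A p53 response to Cre expression stays open, since Cre and the deletion mark the same 3 cultures. The p53 target list had a median of 0.22 and was not called (camera adjusted p = 0.28), so it neither shows nor rules out such a response. Loss of ERK signalling may account for the fall, and with Cre confounded with the group this remains a hypothesis.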

How the results depend on the processing

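The fits without replicate 1 of both groups, with the block and an estimated correlation, and with the block but without a pair were chosen after the data were seen. The count of 1705 genes stayed within 1.5 times under quantile normalization (1844, of which 1603 shared), median subtraction (1820), the level filter (1845), the intensity trend (1649), array weights (1791), both rules for several probe sets (1700 and 1694), the replicate block (2479) and without replicate 1 of both groups (1184). The share of higher calls, 46.6%, was 36.9% after median subtraction, 53.5% with the replicate block, 58.6% with the block but without pair 1, and 35.5% to 51.1% on leaving out each array. Leaving out each array gave 730 to 1331 genes, 539 to 828 genes changed at least 2-fold and 6 to 9 lists, and an adjusted p under 0.01 gave 545 genes, by construction. With the replicate block but without pair 2 or pair 3 the counts were 703 and 806 genes, and without pair 1, 1315 genes changed at least 2-fold; fewer arrays leave fewer degrees of freedom, and why pair 1 differed was not tested. The 8 called lists became 10 with the replicate block, 7 after quantile normalization, 5 with fry, 1 with an estimated correlation and 0 with that and the block, where few degrees of freedom are left. The block called the ERK-responsive early gene and inflammatory lists and Ramp2 in addition, and ended the fry calls of the ERK feedback (0.080) and angiogenic (0.058) lists; it changed no other call among the 55 genes chosen by rule or of a list by camera at the preset correlation, and called further list members as given beside each list. No called value changed sign, while the medians of 6 uncalled lists crossed 0 under some setting, ranging from −0.03 to 0.16 (MAPK components), −0.13 to 0.50 (endothelial), −0.17 to 0.08 (adhesion), −0.02 to 0.50 (matrix proteases), −0.01 to 0.40 (glycolysis) and −0.05 to 0.13 (apoptosis). Of the 52 called named genes 27 passed whichever array was left out and 25 did not; of the 8 lists 6 did. Over the settings that kept camera at the preset correlation and the threshold of 0.05, the block without a pair not counted, 123 values of named genes and 8 of lists lost the threshold and 5 of each gained it. No pseudocount was varied because the values were on a log scale, the leukocyte list had no gene above the level filter, and the targeted genes were not analysed here. Array signal over background was not analysed here.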

Other observations

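All tests given here were chosen after the data were seen, and so were the 4 gene lists of the next paragraph.

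Some complement, proteoglycan and elastic fibre genes not yet described rose in ERK1/2 null cultures. Of 17 complement and acute-phase genes 6 rose and none fell (median 1.83), among them C1ra, the complement C1r protease gene (log2 difference 2.52, SE 0.31, limma adjusted p = 0.0060), and Hpx, which encodes hemopexin (1.35, SE 0.20, limma adjusted p = 0.0098), and with the replicate block 9 rose, Cfb, Cd55 and Clu in addition. Of 11 small leucine-rich proteoglycan genes 4 rose and none fell (median 1.96), Prelp, Podn (2.73), Aspn (1.96) and Omd (1.10), and with the replicate block 7 rose, Dcn, Ogn and Lum in addition. Of 15 elastic fibre genes 3 rose, Fbln5, Eln, the elastin gene (7.12 to 10.85 on the log2 scale, log2 difference 3.74, SE 0.44, limma adjusted p = 0.0054), and Mfap5, and with the block 5 rose, Ltbp4 and Mfap4 in addition; the list median was 0.45, and Eln was the only call among them not described before. Camera gave adjusted p of 0.084, 0.069 and 0.069 for these lists with an estimated correlation.

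Of 19 genes of homologous recombination and the Fanconi pathway 16 were lower, with a list median of −1.84 (camera adjusted p = 0.069 with an estimated correlation, and 0.21 when the block was added). The nuclease gene Exo1 had a log2 difference of −2.50 (SE 0.12), Rad51ap1 of −2.15 (SE 0.12) and Rad54l of −2.03 (SE 0.10), each with a limma adjusted p of 0.0014. The 3 that did not pass were Fancg (−0.09), Dmc1 (0.05) and Fancc (0.34). These 4 lists were picked because their members stood out, so their counts and p-values are no independent test.

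Most endothelial markers gave low signal in these arrays. Only 0.64% of 10000 random lists of the same size had a lower median level, against 99.92% for the fibroblast list, and 16 of the 26 endothelial markers lay in the dimmest 33.3% of genes. Members of both lists ranged in level, but 9 of the 11 fibroblast and 3 of the 26 endothelial markers lay in the brightest 33.3%. In the dimmest 33.3% lay 2 fibroblast markers and 12 of 14 leukocyte markers. In wild type arrays Pecam1, Cdh5 and Kdr stood at 3.77, 3.89 and 3.36 on the log2 scale. The 3 bright endothelial markers, Cd34, Eng and Thbd, stood at 10.10, 9.28 and 8.90. The fibroblast markers Col1a1 and Col1a2 stood at 11.48 and 11.41, and the 2 dim ones, Lum and Postn, at 2.93 and 3.74. Deletion by Cre cannot account for low signal in wild type arrays, whose cultures received a virus without Cre. The endothelial median was 4.16 there and 4.13 in ERK1/2 null arrays, which argues against Cre as the source of the low list level. A further fall of single markers after Cre stays open. The lowest difference between null and wild type arrays was the −0.42 of Kdr, but a fall would hardly show in genes near the floor. A culture in which most RNA came from fibroblast-like cells may account for the levels, but signal is not calibrated between probe sets and no array of a reference endothelial culture was used here, so that probe sets of low response cannot be told apart from it.

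The rise of fibroblast markers was weighed against a change in cell composition. The list rose within each numbered pair, with a lowest median of 0.83. An offset between pairs that both groups share cancels in this comparison, so these medians do not weigh on it. A larger share of fibroblast-like cells stays open: with the replicate block 0 of the 11 markers had a 95% interval wholly below 0. The differences were unequal, from −0.34 for Pdgfra to 4.07 for Dcn, but Pdgfra was already high in wild type (10.49), where a small added population would be hidden. Col1a1 and Col1a2 were high in wild type too, yet a rise was not hidden in them. They differed by 1.06 and 0.82 (95% intervals with the block 0.65 to 1.47 and 0.51 to 1.13). Other accounts are a shift between fibroblast-like subtypes, or a change in matrix transcription within the same cells of the ERK1/2 null cultures. Either may account for the spread of 4.41 on the log2 scale as well. The arrays hold no cell-type labels to separate these.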
